A study of Homo sapiens with 446 samples.

How the data were processed

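Probe-based spatial expression profiles (GeoMx) of 446 regions of fallopian tube tissue were used, from 39 slides and 10 batches. The labels name each region by diagnosis and by epithelium or stroma, and 49 regions, all of batch 1, were the cytokeratin-positive or cytokeratin-negative part of a region. The values are normalized log2 values of 18631 targets that the authors deposited, ranging from -0.18 to 12.78. Genome build GRCh38 is named per the submitters' processing notes; the counting tool, the normalization formula, its offset and the batch correction are not given in the sources used here. From the deposited log2 values, each gene has the same mean in all 10 batches (largest difference 1.2e-13), and the differences between 2 regions of a batch fall on repeated steps, as logged whole counts do, whereas at least 17549 distinct values separate regions of different batches. The authors' table therefore holds values normalized per region and shifted per gene and batch, so a mean level cannot be compared between batches. No whole-number counts were used, and a count model could not be fitted.

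The comparisons, the units, the gene lists, the rule for named genes and most of the alternatives were set before the data were examined, with the test left to follow from the kind of value found. Log2 values called for limma. Columns were matched to samples by slide, region and segment name, with 0 columns left unmatched. A negative control probe and 17 X-inactivation and Y-linked genes were left out, which left 18613 genes, of which 18327 matched a reference symbol, 278 a synonym only and 8 neither. Symbols were used as the table gives them. No pair of regions was identical (0 pairs; highest correlation 0.9512).

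A unit, the replicate throughout, is a slide or the slides that share a case number. This gave 37 units: 25 carry a case code, 2 of them with 2 slides, and 12 are tissue microarrays or uncoded slides with 195 regions. A microarray holds cores of several patients whom the labels do not tie to regions, so such a unit averages over patients, and a patient could be present on more than 1 slide. Groups compared within such a unit may come from different patients. Regions were averaged per unit and group, and limma (lmFit, eBayes with trend and robust; limma 3.58.1, statmod 1.5.0, data.table version 1.17.8, R 4.3.3) was fitted to the averages with the unit as a fixed block. The 5 epithelial groups shared a fit, as the 5 stromal groups did, so units that hold 1 of the 2 groups of a comparison beside another group also contribute to its difference; counts of units are of those that hold both. Epithelium and stroma of NFT were compared in a fit of their own, and the difference of the STIC change between epithelium and stroma was taken per unit and tested against 0. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Pairing by unit comes from the slide and case names. As a check, deviations from the group means, averaged over genes, correlated within units at 0.199 (STIC and NFT), 0.246 (STIL and NFT), 0.115 (HGSC and NFT), 0.185 (p53 signature and NFT), 0.0879 (STIC and STIL) and 0.289 (HGSC and STIC) in epithelium, and at 0.166, 0.216 and 0.0352 for stroma beside STIC, STIL and HGSC. Between different units the means lay from -0.0602 to -0.00237.

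Fixed lists of genes, 26 in number, were tested with camera at a preset correlation between genes of 0.01, adjusted over the 26 lists of a comparison. Beside it stand camera with an estimated correlation and the percentile of the list's median among 10000 random lists of the same size, drawn in 20 bins of mean level and read as a 2-sided p adjusted the same way. Of 137 calls among 286 list tests, 61 held with the estimated correlation and 106 against random lists. Named genes were, per comparison, the 6 largest rises and 6 largest falls among called genes that moved that way in at least 75% of units (a share of 0.75), up to 4 members with the smallest p of each list described, and a fixed panel of markers, of which 1 gene is not reported here. The change per unit of 7 lists in lesion and stroma was related by Pearson and Spearman correlation with 1e+05 permutations, two-sided. Differences of list means between epithelium and stroma used exact sign flips (2048 over 11 units).

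Total counts per region are not in the table, so the fewest distinct steps between a region and any other region of its batch stood in for depth. This number ran from 38 to 6033, median 666, and depends on the other regions of the batch. Batch medians ran from 236.5 (batch 3_1) to 2043 (batch 2_1). Signal over background was judged against the 379 olfactory receptor genes (mean 2.41, 95th percentile 3.08; chosen after the data were seen) and the negative probe (mean 1.76). The median gene had a mean of 2.87, so most genes lie near the background, and 7489 lie above that percentile.

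The method was tested on simulated data with the real genes, units and spread, in which 200 of 18613 genes were changed by log2 0.5, 1 or 2. For a change of 0.5, limma recovered 85.1% of planted genes for STIC against NFT, 85.1% for STIL against NFT, 52.2% for HGSC against NFT, 2.99% for the p53 signature, 62.7% for STIC against STIL, 38.8% for HGSC against STIC, 50.7% for epithelium against stroma, and 22.4%, 31.3% and 2.99% for stroma beside STIC, STIL and HGSC. For a change of 1 the shares were 100%, 98.5%, 97%, 65.7%, 98.5%, 100%, 97%, 94%, 97% and 29.9% in the same order, and for a change of 2 at least 98.5%. False calls made up 2.63% to 5.38% of all calls. The noise was drawn independently for each gene, so these shares may not hold for real genes, which vary together.

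Alternatives were a filter on genes of the lowest mean levels, quantile normalization, scaling to the median gene, no replicate block, the slide as unit, regions as samples with the unit as a random block, weights by number of regions, case-coded slides only, leaving out batch 1, batch series 2 or 3 alone, leaving out the tenth of regions with the fewest steps, leaving out stroma whose diagnosis differs from that of its epithelial partner (3 regions), leaving out each unit of the p53 signature and of stroma beside HGSC in turn, and STIL alone for the relation of lesion and stroma. Steps took the place of the planned measure of the poorest regions, since the table has no common lowest value. In the list tests of the alternatives, camera took neither the random block nor the weights by number of regions. Added after the data were seen were leaving out 1 stromal region of another batch, leaving out batch 3_1, testing only genes above the olfactory level, steps as a covariate, a fit of only the 2 groups of a comparison in the units that hold both, and the relation within batch series. A subset that left 1 unit in a comparison is not given, a limit set after the values were seen, because such a value belongs to one person. Regions of mesothelium (4), endometrioid carcinoma (1), endometrial endometrioid carcinoma (2) and clear cell carcinoma (1), and the stroma beside them, entered no fit because they came from 1 or 2 units; the mesothelium was only set beside the NFT regions of its slide.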

Results

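Gene expression was measured in 446 captured regions of human fallopian tube tissue with the GeoMx spatial platform. In this assay, probes bound to the RNA of a tissue section carry indexing oligonucleotides that ultraviolet light releases from a chosen area for sequencing. The regions came from 39 slides, grouped here into 37 units, a unit being a slide or the slides that share a case number. Normal-looking tubal epithelium (NFT) was captured in 99 regions of 37 units. Serous tubal intraepithelial carcinoma (STIC), a lesion confined to the tubal lining, had 102 regions in 27 units. Serous tubal intraepithelial lesion (STIL), an atypical epithelium that falls short of STIC, had 60 regions in 24 units. High grade serous carcinoma (HGSC) had 29 regions in 13 units, and the p53 signature, a run of tubal cells marked by its stain without atypia, had 4 regions in 4 units. Stroma was captured beside NFT (56 regions, 22 units), STIC (40 regions, 11 units), STIL (33 regions, 16 units), HGSC (7 regions, 3 units) and the p53 signature (2 regions, 2 units). Regions of mesothelium, of endometrioid and clear cell carcinomas and of the stroma beside them entered no fit.

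The table held normalised log2 values of 18631 targets in 10 batches, and the total count of each region is not known from it. Distinct steps were counted between the values of a region and those of every other region of its batch, and the fewest stood in for its depth. This number ranged from 38 to 6033 with a median of 666. The group medians were 681 for NFT, 749 for STIL, 1338 for STIC, 1684 for HGSC and 611.5 for the p53 signature. In stroma the medians were 410.5 beside NFT, 455 beside STIL, 458 beside STIC and 625 beside HGSC. These medians pool the batches, whose own medians ran from 236.5 to 2043, so they mix depth with batch. The 379 olfactory receptor genes, a family expressed mainly in nasal epithelium, had a mean level of 2.41, and 7489 of the 18613 tested genes lay above their 95th percentile of 3.08. That background level was chosen after the data were seen. The mean of every gene was equal in the 10 batches (largest difference 1.2e-13), so only differences between regions of one batch carry information. The main fits took the unit as a block. The 2 cases with 2 slides each span 2 batches, however, and their regions were averaged over both. The 5 epithelial groups shared a fit, as the 5 stromal groups did, so a fitted difference also draws on units that held 1 of its 2 groups beside another group. The units given with a comparison are those that held both groups, and an alternative added after the data were seen fitted those units and groups alone. All differences are log2 with the standard error (SE) of the limma fit and its adjusted p. For a gene list the median difference of its genes is given with the adjusted p of camera, limma's list test. Where a bracket holds only 2 values after a list's name, they are that median and that adjusted p.

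**Figure D1:**
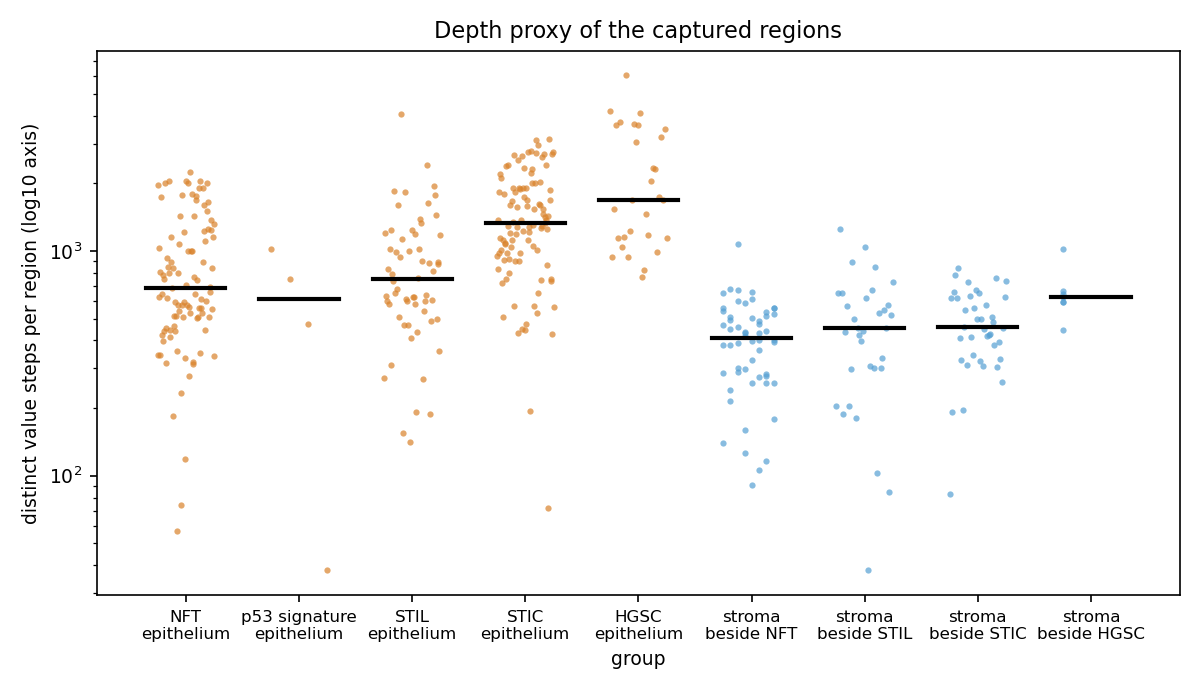
Number of distinct value steps per region (vertical axis, log10 scale) for each group (horizontal axis); each point is one region and the bar is the median. The medians of these groups run from 410.5 in stroma beside NFT to 1684 in HGSC.

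Epithelial and stromal regions of NFT were compared in 22 units to ask how far the captured regions separated the 2 compartments. DCN (decorin, -3.25 ± 0.13), SFRP4 (-3.43 ± 0.15), IGFBP5 (-3.18 ± 0.13) and the smooth muscle actin gene ACTA2 (-2.86 ± 0.14) were lower in epithelium in 22 of 22 units. CAPS (3.49 ± 0.16), WFDC2, which encodes the serum marker HE4 (3.44 ± 0.14), SLPI (3.43 ± 0.18), MUC1 (3.41 ± 0.14) and PAX8, a transcription factor of secretory cells (3.15 ± 0.14), were higher in 22 of 22. Keratin and junction genes were higher for 16 of 17 (17 adjusted over the list alone; median 1.98, adjusted p = 5.26e-26), among them KRT8 (2.52 ± 0.14) and EPCAM (1.86 ± 0.15). Ciliated cell genes were higher for 39 of 40 (39 adjusted over the list alone; median 1.70, adjusted p = 5.61e-38), as FOXJ1, the master regulator of motile cilia (2.87 ± 0.21), was. Matrix genes were lower for 19 of 19 (19 adjusted over the list alone; median -2.0, adjusted p = 7.46e-32), among them COL1A1 (-2.15 ± 0.15) and COL3A1 (-2.78 ± 0.16). Smooth muscle genes were lower for 10 of 10 (10 adjusted over the list alone; median -1.71, adjusted p = 2.8e-18) and endothelial genes for 13 of 14 (14 adjusted over the list alone; median -0.90, adjusted p = 1.55e-10). All of these list calls held with an estimated correlation, at adjusted p of 0.0119 or less.

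Epithelium also held more transcript of oxidative phosphorylation genes (32 of 35 higher, 34 adjusted over the list alone; median 0.89, adjusted p = 8.88e-19) and of MHC class II genes (10 of 13 higher, 11 adjusted over the list alone; median 0.76, adjusted p = 3.18e-08), the latter including CD74 (1.66 ± 0.14) and HLA-DRA (1.57 ± 0.14). The class II call had an adjusted p of 0.0304 with an estimated correlation and of 0.0558 against random lists of like level. Secretory cell genes were higher for 14 of 19 (14 adjusted over the list alone; median 1.45, adjusted p = 1.19e-12; 0.000902 with an estimated correlation). MHC class I genes were higher as a list (0.46, 0.00822; adjusted p = 0.168 with an estimated correlation), but quantile normalization turned that median to -0.17. B and plasma cell genes were lower for 7 of 14 (8 adjusted over the list alone; median -0.67, adjusted p = 0.001; adjusted p = 0.168 with an estimated correlation). T and NK cell genes (median -0.27, adjusted p = 0.0152) and macrophage genes (median -0.26, adjusted p = 0.0414) were lower as lists, and both calls were lost with an estimated correlation (adjusted p = 0.148 and 0.168). The olfactory genes, taken as background, had a median of -0.232 themselves. In NFT epithelium 0 of 18 T and NK cell markers and 4 of 17 macrophage markers lay above the olfactory level. Fewer immune transcripts cannot be told apart here from a shift of the background. limma called 7038 genes, 3720 higher and 3318 lower in epithelium. Scaling each region to its median gene turned the balance of these calls from 52.9% higher to 73.6% higher, so the balance rests on the scaling. Epithelium had more steps in 18 of 22 units (log2 difference 0.253), and 119 of the 379 olfactory genes were among those called.

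STIC was compared with NFT, with both in 27 units, to ask what changes in the earliest carcinoma of the tube. Genes of cell division and of serous carcinoma rose, and genes of ciliated cells fell. STMN1, which encodes the microtubule regulator stathmin, rose 4.90-fold (log2 2.29 ± 0.21, adjusted p = 1.98e-13, higher in 26 of 27 units). The histone genes H3C2 (2.16 ± 0.23), H1-5 (1.93 ± 0.21) and H3C7 (1.65 ± 0.20) were among the 6 largest rises, with MARCKSL1 (1.80 ± 0.16) and the troponin gene TNNT1 (1.66 ± 0.19). Histone genes have near-identical copies, so the value of a single one is uncertain. CRISP3, which encodes a secreted protein, fell 10.8-fold (log2 -3.43 ± 0.38, lower in 24 of 27 units). Next came the ciliary genes C20orf85 (-3.13 ± 0.27), TPPP3 (-3.05 ± 0.29) and CFAP157 (-2.78 ± 0.22), AGR2, a secretory cell disulfide isomerase (-2.92 ± 0.28), and SPATA18 (-2.67 ± 0.19).

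Ciliated cell genes fell for 38 of 40 (39 adjusted over the list alone), with a median of -1.60 and lower list means in 27 of 27 units (adjusted p = 3.75e-59). DNAH9, a dynein of the ciliary arm, fell by 2.25 ± 0.17 and FOXJ1 by 1.84 ± 0.24. Proliferation genes rose for 29 of 34 (33 adjusted over the list alone; median 0.45, adjusted p = 3.98e-14), with CKS2 (1.26 ± 0.15), UBE2C (1.07 ± 0.15), CDK1 (0.86 ± 0.12) and MKI67, the gene of the Ki-67 antigen (0.54 ± 0.12). Of those 34 genes, 30 had a mean level no higher than the olfactory background. DNA replication genes rose for 14 of 23 (16 adjusted over the list alone; median 0.34, adjusted p = 3.78e-08), with MCM7 (1.01 ± 0.12), MCM6 (0.89 ± 0.13) and PCNA (0.84 ± 0.13). Serous carcinoma markers rose for 20 of 28 (20 adjusted over the list alone; median 0.68, adjusted p = 2.1e-12). HMGA1 (1.19 ± 0.14), the laminin gene LAMC1 (1.03 ± 0.12), CCNE1, which encodes cyclin E1 (0.68 ± 0.11), and CDKN2A, which encodes p16 (0.71 ± 0.23, adjusted p = 0.0128), were among them. CDKN2A was the exception within batches, with -0.24 in the 7 units of series 3. These 4 list calls held with an estimated correlation, at adjusted p = 0.00199, 0.0474, 0.023 and 0.000265 in the order given. Homologous recombination and Fanconi genes rose for 8 of 18 (8 adjusted over the list alone; median 0.20, adjusted p = 0.00203; adjusted p = 0.0696 with an estimated correlation), RAD51AP1 (0.57 ± 0.11) and CHEK1 (0.41 ± 0.10) included.

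MHC class II genes fell in STIC for 9 of 13 (10 adjusted over the list alone; median -0.65, adjusted p = 0.00146; adjusted p = 0.408 with an estimated correlation). CTSS, a protease that prepares class II molecules (-1.25 ± 0.20), HLA-DPA1 (-0.99 ± 0.25), CD74 (-0.85 ± 0.22) and HLA-DRA (-0.84 ± 0.24) fell, the list mean was higher than in NFT in 7 of 27 units, and IFI30 rose (0.80 ± 0.16). Genes of p53 targets fell for 6 of 22 and rose for 1 (6 and 1 adjusted over the list alone; median -0.20, adjusted p = 0.002; adjusted p = 0.0856 with an estimated correlation). CDKN1A, which encodes p21, fell by 1.36 ± 0.20 and MDM2 by 0.48 ± 0.12. Steroid hormone response genes fell for 5 of 17 (5 adjusted over the list alone; median -0.24, adjusted p = 0.0043; adjusted p = 0.0856 with an estimated correlation), TFF3, a trefoil factor (-1.71 ± 0.28), and PER1 (-0.67 ± 0.12) among them. Secretory cell genes went both ways, 6 rising and 8 falling of 19 (adjusted p = 0.583): PAX8 (0.60 ± 0.13) and KRT7 (1.26 ± 0.17) rose, whereas OVGP1, oviductal glycoprotein (-1.46 ± 0.41), and ALDH1A1 (-1.68 ± 0.15) fell.

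Lists of metabolism and epithelial structure rose less firmly. Oxidative phosphorylation genes rose for 12 of 35 (13 adjusted over the list alone; median 0.20, adjusted p = 0.000782), cholesterol and fatty acid genes for 6 of 17 (6 adjusted over the list alone; median 0.19, adjusted p = 0.0126) and keratin and junction genes for 8 of 17 (9 adjusted over the list alone; median 0.25, adjusted p = 0.0126). With an estimated correlation these calls were lost (adjusted p = 0.403, 0.273 and 0.403), as they were against random lists of like level (0.983, 0.213 and 0.553). NDUFB9 (0.99 ± 0.12), a complex I subunit gene, and CLDN4 (0.98 ± 0.13), a claudin gene, are examples. No call was made for the lists of type I interferon response (median 0.17, adjusted p = 0.162), MHC class I (-0.03, 0.821), immediate early genes, the first genes a stimulus induces (-0.14, 0.712), glycolysis and hypoxia (0.14, 0.366) and mesenchymal transition (0.10, 0.495). Lists of other cell types were not called either: matrix (-0.11, 0.168), activated fibroblasts (0.01, 0.622), smooth muscle (-0.04, 0.722), endothelium (-0.05, 0.465), T and NK cells (-0.00, 0.622), B and plasma cells (-0.06, 0.617), macrophages (0.11, 0.541), mesothelium (-0.16, 0.168) and erythrocytes and platelets (-0.18, 0.162). limma called 5344 genes, 3162 higher and 2182 lower in STIC, of which 81 rose and 215 fell by more than 1 log2 unit. STIC had more steps in 26 of 27 units (log2 difference 0.462 ± 0.296, SD), and with the number of steps as a covariate, an alternative added after the data were seen, 2813 genes passed. Within batch series 2 (19 units) 4419 genes passed, and within series 3 (7 units) 724.

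**Figure D2:**
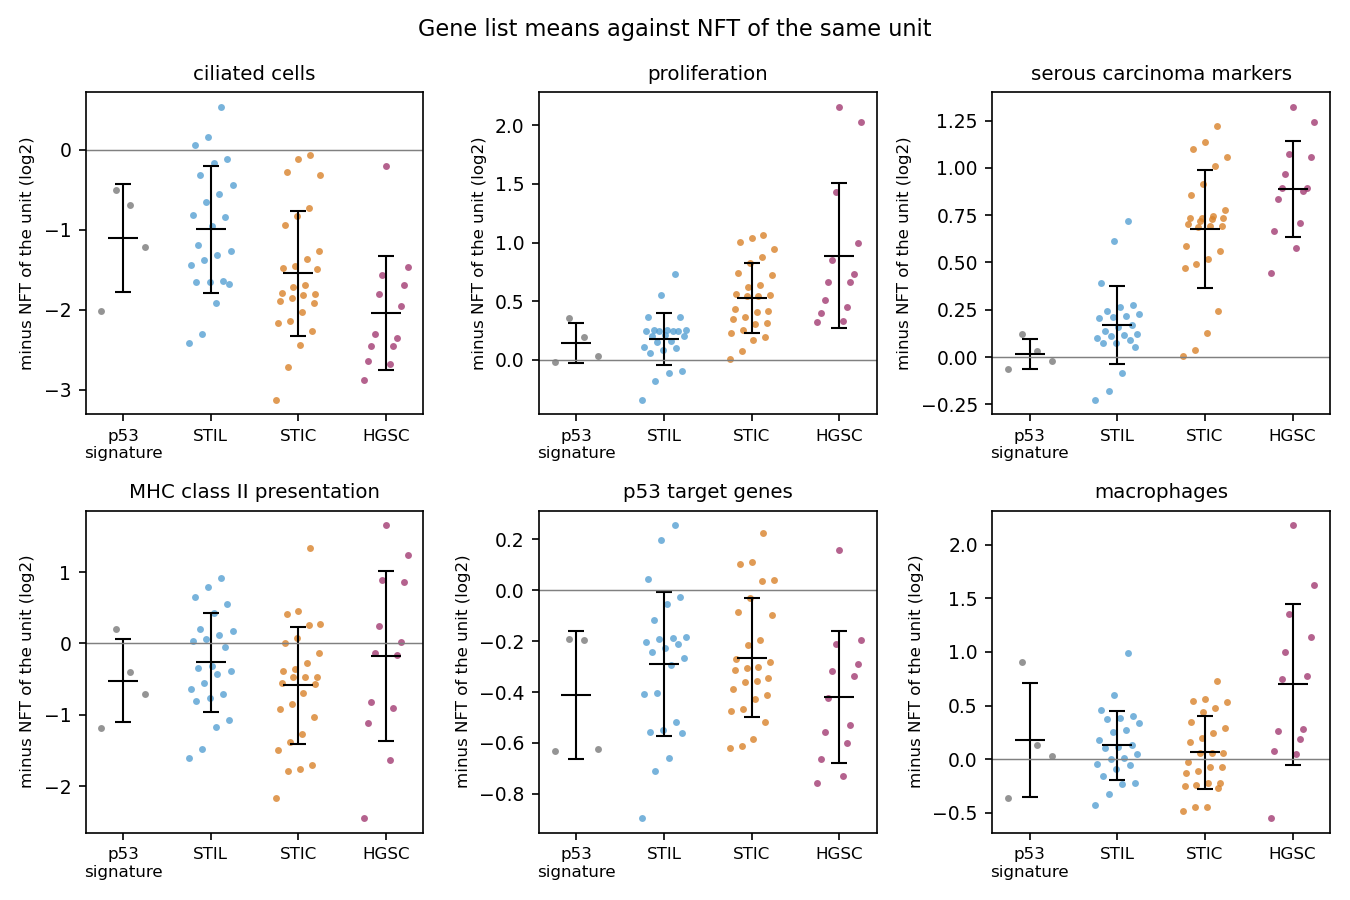
Difference of the list mean from NFT of the same unit (vertical axis, log2) for 6 gene lists (panels) in STIL, STIC, HGSC and the p53 signature (horizontal axis); each point is one unit and bars are the mean and SD over units. Ciliated cell genes are lower in 27 of 27 units with STIC and 13 of 13 with HGSC.

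STIL was compared with NFT in 24 units to ask which changes precede STIC. MYC (1.30 ± 0.18), JUN (1.14 ± 0.21, higher in 24 of 24 units), STMN1 (1.26 ± 0.22), MARCKSL1 (1.19 ± 0.17), the adenylate cyclase gene ADCY8 (1.42 ± 0.18) and SHANK1 (1.07 ± 0.22) were the 6 largest rises. AGR2 (-2.27 ± 0.29), TPPP3 (-1.95 ± 0.30), LRRC46 (-1.90 ± 0.23), C9orf24 (-1.88 ± 0.24), AK1 (-1.81 ± 0.24) and PAX2, a transcription factor of Müllerian epithelium (-1.78 ± 0.29, lower in 24 of 24 units), were the largest falls. Ciliated cell genes fell for 37 of 40 (38 adjusted over the list alone; median -1.07, adjusted p = 6.61e-50; 0.012 with an estimated correlation), DNAH9 by 1.71 ± 0.17 and FOXJ1 by 1.49 ± 0.25. Targets of p53 fell for 9 of 22 and rose for 1 (11 and 1 adjusted over the list alone; median -0.26, adjusted p = 1.55e-05; 0.0226 with an estimated correlation), among them CDKN1A (-1.15 ± 0.21), ZMAT3 (-0.68 ± 0.12) and MDM2 (-0.59 ± 0.13).

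Proliferation genes rose for 4 of 34 in STIL (4 adjusted over the list alone; median 0.19, adjusted p = 7.45e-05), as CKS2 (0.85 ± 0.15) and CDC20 (0.43 ± 0.13) did, and MKI67 did not pass (0.20 ± 0.13, adjusted p = 0.364). The lists of DNA replication (0.16, 0.00545), Fanconi repair (0.13, 0.0244), serous carcinoma markers (0.12, 0.0353) and immediate early genes (0.14, 0.0171) were higher, with 6, 4, 6 and 4 genes up when adjusted over the list alone. Those of MHC class II (-0.44, 0.0244), secretory cells (-0.41, 0.0448) and matrix (-0.18, 0.0353) were lower, with 4, 9 and 2 genes down when adjusted over the list alone. None of these 8 calls held with an estimated correlation, proliferation included (adjusted p between 0.382 and 0.64), and the serous and immediate early calls were also lost against random lists (0.0934 and 0.247). Genes behind them are FANCA (0.38 ± 0.10), SOX17 (0.80 ± 0.17), JUND (0.60 ± 0.17), CTSS (-0.96 ± 0.20), LCN2 (-1.55 ± 0.27) and DCN (-0.61 ± 0.14). The fall of KRT19 (-1.16 ± 0.16) and the rise of VIM (0.83 ± 0.22) passed, whereas LAMC1 (0.24 ± 0.12, adjusted p = 0.218), CCNE1 (0.23 ± 0.12, adjusted p = 0.211) and CDKN2A (-0.24 ± 0.24, adjusted p = 0.578) did not. limma called 2360 genes, 873 higher and 1487 lower. STIL had more steps in 14 of 24 units (log2 difference 0.19), and 2181 genes passed with steps as a covariate. Within series 2 (11 units) 1185 genes passed and within series 3 (9 units) 405, where the median of the class II list was -0.02 and its test turned.

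STIC was compared with STIL in the shared fit, and 14 units held both lesions. Serous carcinoma markers were higher in STIC for 15 of 28 (16 adjusted over the list alone; median 0.57, adjusted p = 6.32e-13; 0.000158 with an estimated correlation), among them MUC16, the gene of the CA-125 antigen (1.34 ± 0.26), the cancer testis gene PRAME (1.21 ± 0.23), LAMC1 (0.79 ± 0.14) and CDKN2A (0.96 ± 0.27). ATP6V1B1 (1.72 ± 0.27), IGFBP2 (1.47 ± 0.25), COL4A2 (1.32 ± 0.27), ITM2C (1.30 ± 0.30) and H3C2 (1.25 ± 0.27) completed the 6 largest rises. CRISP3 (-1.80 ± 0.46), C20orf85 (-1.37 ± 0.33), SHANK1 (-1.36 ± 0.25), VWA3A (-1.30 ± 0.25), CLEC11A (-1.19 ± 0.23) and TSPAN8 (-1.11 ± 0.19) were the largest falls. The progesterone receptor gene PGR was lower (-0.99 ± 0.27, adjusted p = 0.0156, lower in 11 of 14 units), as OVGP1 was (-1.69 ± 0.49, adjusted p = 0.0228).

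Higher in STIC than STIL were the lists of keratins and junctions (10 of 17 genes, median 0.58, adjusted p = 7.16e-08), proliferation (7 of 34, 0.27, 2.67e-09), oxidative phosphorylation (9 of 35, 0.28, 4.21e-08), DNA replication (8 of 23, 0.19, 1.53e-05) and cholesterol synthesis (6 of 17, 0.32, 4.78e-05). Adjusted over the list alone, 11, 13, 13, 9 and 9 of their genes passed. EPCAM (0.76 ± 0.16), UBE2C (0.77 ± 0.18), NDUFB9 (0.96 ± 0.15), MCM4 (0.76 ± 0.14) and SQLE (0.68 ± 0.14) represent them in that order. Interferon genes (6 of 38, median 0.22, adjusted p = 0.000748) and glycolysis genes (5 of 21, 0.18, 0.0226) were also higher, with IFI6 (1.10 ± 0.30) and NDRG1 (0.94 ± 0.18), and each had 6 genes up when adjusted over the list alone. Lower were ciliated cell genes (13 of 40, median -0.52, adjusted p = 8.8e-18), immediate early genes (1 of 17, -0.28, 0.000748) and steroid response genes (3 of 17, -0.14, 0.00783), with TEKT2 (-0.74 ± 0.17), EGR3 (-0.81 ± 0.27) and GREB1 (-0.45 ± 0.14). Their falls numbered 23, 0 and 3 when adjusted over the list alone. With an estimated correlation none of these 10 calls held (adjusted p between 0.0695 and 0.479), and those of oxidative phosphorylation and glycolysis were also lost against random lists (0.079 and 0.36). limma called 1286 genes, 961 higher and 325 lower. STIC had more steps in 12 of 14 units (log2 difference 0.356), and 332 genes passed with steps as a covariate. With only the 14 units that held both in the fit 365 genes passed, and 12 of the 27 genes named for this comparison lost their call, PRAME, CDKN2A, CRISP3, PGR and OVGP1 among them, as the glycolysis list did (adjusted p = 0.139); MUC16 (1.54) and LAMC1 (0.80) passed. In series 2 (11 units) 611 genes passed, and in series 3 (2 units) limma called 0 (1318 at an unadjusted p below 0.05).

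HGSC was compared with NFT in 13 units to describe the invasive tumour. The largest rises were in the histone genes H3C2 (2.47 ± 0.30), H1-5 (2.44 ± 0.28), H3C15 (2.40 ± 0.23), H3C7 (2.20 ± 0.26) and H3C13 (2.17 ± 0.23) and in the interferon-induced gene BST2 (2.31 ± 0.38). TPPP3 fell 19.8-fold (log2 -4.30 ± 0.38, lower in 13 of 13 units), followed by CRISP3 (-4.06 ± 0.51), C20orf85 (-3.72 ± 0.37), AGR2 (-3.56 ± 0.38), CFAP157 (-3.47 ± 0.29) and SPATA18 (-3.43 ± 0.26). Ciliated cell genes fell for 38 of 40 (38 adjusted over the list alone; median -1.92, adjusted p = 3.2e-63; 0.00124 with an estimated correlation). Proliferation genes rose for 32 of 34 (32 adjusted over the list alone; median 0.81, adjusted p = 9.07e-22; 0.00625 with an estimated correlation), with TPX2 (1.37 ± 0.16), CDK1 (1.35 ± 0.16) and MKI67 (1.14 ± 0.17). Serous carcinoma markers rose for 18 of 28 (21 adjusted over the list alone; median 0.77, adjusted p = 2.67e-12; 0.000286 with an estimated correlation), with PRAME (2.00 ± 0.26), HMGA1 (1.48 ± 0.18) and LAMC1 (1.12 ± 0.16). DNA replication genes rose for 17 of 23 (19 adjusted over the list alone; median 0.48, adjusted p = 8.74e-11), Fanconi repair genes for 11 of 18 (15 adjusted over the list alone; 0.38, 2.03e-05) and glycolysis genes for 13 of 21 (14 adjusted over the list alone; 0.50, 9.09e-05). These calls held with an estimated correlation (0.00483, 0.00725 and 0.0385). MCM7 (1.33 ± 0.15), RAD51AP1 (0.91 ± 0.15) and ENO1 (1.34 ± 0.17) are members.

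In HGSC, p53 targets fell for 8 of 22 (9 adjusted over the list alone; median -0.20, adjusted p = 0.00028; 0.0385 with an estimated correlation), CDKN1A by 1.73 ± 0.27 and BTG2 by 1.42 ± 0.28. Steroid response genes fell for 4 of 17 (4 adjusted over the list alone; median -0.32, adjusted p = 0.000642; 0.0385 with an estimated correlation), TFF3 by 2.21 ± 0.38 and PER1 by 1.13 ± 0.16. Immediate early genes fell for 10 of 17 (12 adjusted over the list alone; median -0.55, adjusted p = 3.49e-08; adjusted p = 0.0822 with an estimated correlation), NR4A1 by 2.94 ± 0.39 and ATF3 by 2.23 ± 0.41. Genes of stromal and immune cells were also higher in the HGSC regions: macrophages for 14 of 17 (16 adjusted over the list alone; median 0.70, adjusted p = 2.3e-08; adjusted p = 0.0553 with an estimated correlation), with APOE (1.62 ± 0.24) and CD68 (0.84 ± 0.17), and activated fibroblasts for 6 of 16 (6 adjusted over the list alone; 0.29, 0.000801; 0.0492 with an estimated correlation), with MMP11 (1.05 ± 0.14). Type I interferon genes rose for 21 of 38 (23 adjusted over the list alone; median 0.52, adjusted p = 3.57e-07; adjusted p = 0.2 with an estimated correlation), with ISG15 (1.95 ± 0.33), and MHC class I genes for 11 of 17 (13 adjusted over the list alone; 0.67, 0.000419; adjusted p = 0.249 with an estimated correlation), with HLA-C (0.84 ± 0.19). Oxidative phosphorylation (21 of 35, median 0.45, adjusted p = 6.33e-08), mesenchymal transition (5 of 15, 0.33, 0.00626) and cholesterol genes (6 of 17, 0.26, 0.0109) rose as lists, with 23, 7 and 6 genes adjusted over the list alone and FN1 (2.03 ± 0.24) among the second. These 3 calls were lost with an estimated correlation (adjusted p = 0.102, 0.102 and 0.174), and the cholesterol call against random lists (0.15).

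The matrix list was not called in HGSC against NFT (8 of 19 rose and 3 fell, median 0.33, adjusted p = 0.327), nor was MHC class II (median -0.23, adjusted p = 0.733). limma called 4562 genes, 2997 higher and 1565 lower. HGSC had more steps in 13 of 13 units (log2 difference 0.986), so depth and diagnosis point the same way in every unit. With steps as a covariate 1384 genes passed, and 40.3% of them were higher in place of 65.7%. The lists of class I (0.14, 0.652), oxidative phosphorylation (0.20, 0.0709) and cholesterol (0.07, 0.6) were then no longer called, nor were BST2 (1.25, adjusted p = 0.182), CD68 and HLA-C, and the class II list was called as lower (-1.09, adjusted p = 1e-05). Quantile normalization also lowered the share of higher genes, to 55%. Within series 2 (11 units) 4319 genes passed. The case-coded slides held only 2 units, with 383 genes and a mesenchymal transition median of -0.02. In the other units, microarrays or uncoded slides, the HGSC and NFT regions may come from different patients.

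**Figure D3:**
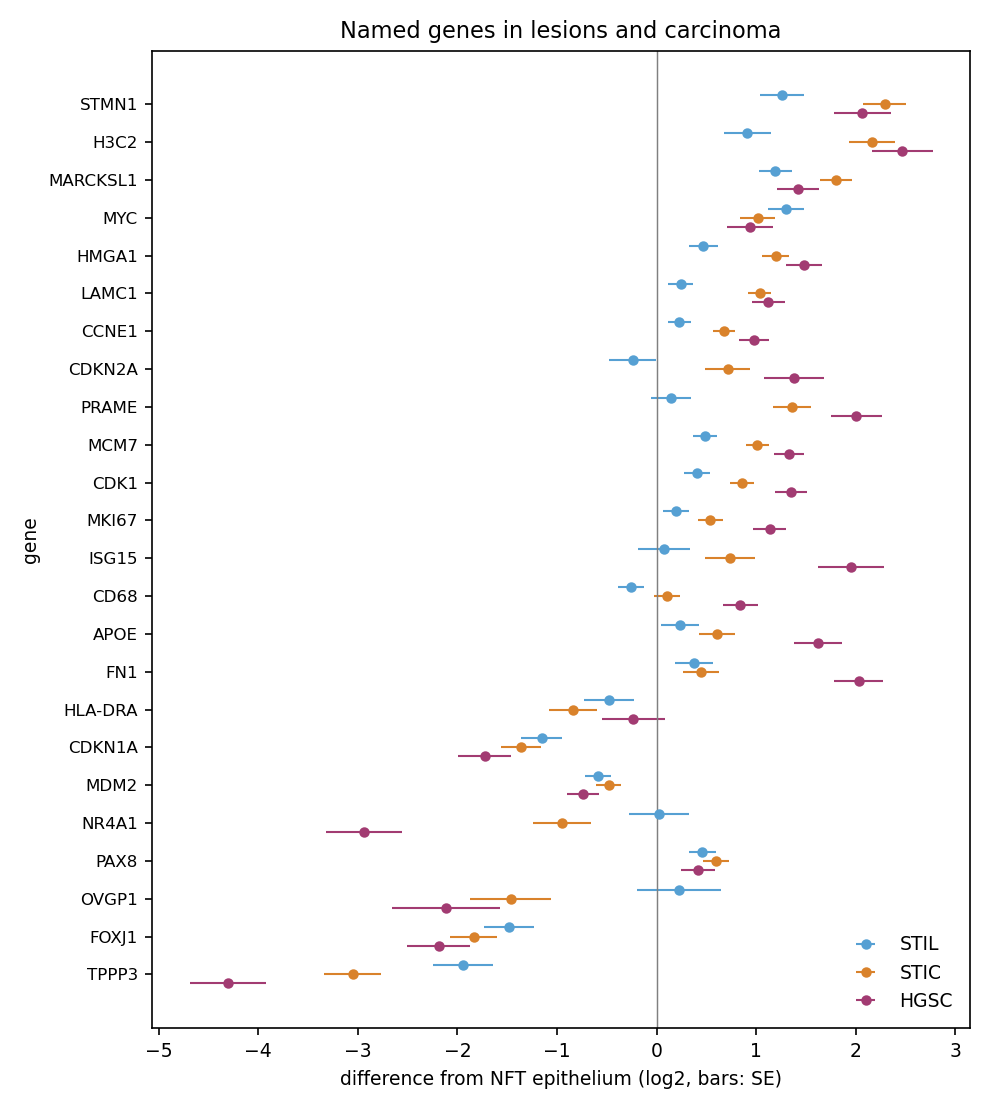
Log2 difference from NFT (horizontal axis) of 24 named genes (vertical axis) in STIL, STIC and HGSC (24, 27 and 13 units); points are the fitted difference and bars its SE. FOXJ1 fell by 1.49, 1.84 and 2.19 and STMN1 rose by 1.26, 2.29 and 2.06.

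HGSC was compared with STIC in the shared fit, with both in 13 units, to ask what separates invasion from the intraepithelial lesion. Matrix and macrophage genes were higher and immediate early genes lower in HGSC. Fibronectin FN1 (1.58 ± 0.25, higher in 13 of 13 units), osteopontin SPP1 (1.53 ± 0.29), COL1A1 (1.5 ± 0.21), COL3A1 (1.27 ± 0.23), IFI30 (1.26 ± 0.21) and SULF1 (1.23 ± 0.20) were the largest rises. ATF3 (-2.04 ± 0.42), NR4A1 (-1.99 ± 0.39), ZFP36 (-1.54 ± 0.35), TBX2 (-1.34 ± 0.29), SLC25A25 (-1.25 ± 0.21) and RRAD (-1.11 ± 0.25) were the largest falls. Macrophage genes were higher for 7 of 17 (15 adjusted over the list alone; median 0.60, adjusted p = 1.47e-25), activated fibroblast genes for 2 of 16 (5 adjusted over the list alone; 0.25, 2.37e-09) and glycolysis genes for 3 of 21 (12 adjusted over the list alone; 0.39, 4.6e-11). Immediate early genes were lower for 4 of 17 (12 adjusted over the list alone; -0.999, 3.61e-28). These 4 calls held with an estimated correlation, each at adjusted p = 0.000494. Further members are TYROBP (0.76 ± 0.16), CD163 (0.59 ± 0.13), MMP11 (1.04 ± 0.15) and ALDOA (0.78 ± 0.16).

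MHC class I genes were higher in HGSC than STIC for 4 of 17 (10 adjusted over the list alone; median 0.43, adjusted p = 1.73e-14; 0.0141 with an estimated correlation), among them B2M (0.95 ± 0.21) and HLA-B (0.97 ± 0.21). The lists of interferon response (median 0.41, adjusted p = 2.63e-15), proliferation (0.35, 2.94e-14), matrix (0.29, 2.23e-06), mesenchymal transition (0.25, 1.33e-05), B and plasma cells (0.24, 7.85e-07), Fanconi repair (0.19, 0.000423), DNA replication (0.18, 1.27e-05) and mesothelium (0.17, 0.00476) were higher. These held with an estimated correlation at adjusted p of 0.0363 or less, and 11 interferon, 15 proliferation, 7 matrix and 5 B and plasma cell genes were up when adjusted over the list alone. With only genes above the olfactory level tested, the mesenchymal test turned. MHC class II (median 0.49, adjusted p = 1.45e-07), oxidative phosphorylation (0.23, 2.89e-07), serous carcinoma markers (0.14, 0.0112) and T and NK cells (0.10, 0.0472) were higher too, and ciliated cells (-0.34, 1.41e-14), keratins and junctions (-0.12, 0.000176), steroid response (-0.08, 0.0395) and p53 targets (-0.03, 0.0395) lower; with an estimated correlation these 8 calls were lost (adjusted p between 0.0925 and 0.277), and those of steroid response, p53 targets and T and NK cells also against random lists (0.0652, 0.231 and 0.0652). Falls of CDH1, E-cadherin (-0.67 ± 0.17, lower in 13 of 13 units), and CLDN4 (-0.71 ± 0.18) passed, and MKI67 did not (0.60 ± 0.17, adjusted p = 0.105). limma called 74 genes, 53 higher and 21 lower. HGSC had more steps in 13 of 13 units (log2 difference 0.547); 33 genes passed with steps as a covariate, with the class II (0.05, 0.612), serous (-0.02, 0.612) and oxidative phosphorylation calls (0.05, 0.279) lost. B2M, HLA-B, CD163, TYROBP, SPP1, IFI30, CDH1 and CLDN4 no longer passed there, while FN1, COL1A1, ATF3 and NR4A1 did. With only the 13 units that held both in the fit 20 genes passed. FN1, SPP1, IFI30, MMP11, B2M and HLA-B kept their calls and the other 14 named genes that had passed lost theirs. The ciliated median was then -0.10 (adjusted p = 9.44e-07) in place of -0.34, that of p53 targets turned to 0.06 (0.638), and the serous (0.202) and steroid calls (0.298) were lost. In the 2 case-coded units 12 genes passed and the medians of interferon (-0.11), matrix (-0.08), mesenchymal transition (-0.02), mesothelium (-0.17), macrophage (-0.04) and T and NK cell genes (-0.05) were below 0. In the other units the HGSC and STIC regions may come from different patients.

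The p53 signature was compared with NFT in 4 units. ARL9 (1.92 ± 0.27, adjusted p = 9.47e-06), the metallothionein gene MT1G (2.09 ± 0.56), DMBT1 (1.47 ± 0.34), GUCY1A2 (1.38 ± 0.37) and ARPC5 (1.19 ± 0.24) were higher in 4 of 4 units and IGFBP3 (1.41 ± 0.33) in 3 of 4. PAX2 (-2.20 ± 0.63), SHANK2 (-1.45 ± 0.25), IFT57 (-1.40 ± 0.29), C4orf47 (-1.36 ± 0.29) and RPS27L (-1.32 ± 0.30) were lower in 4 of 4, and RIBC1 (-1.43 ± 0.32) in 3 of 4. Ciliated cell genes fell for 2 of 40 (18 adjusted over the list alone; median -0.82, adjusted p = 1.17e-12). Lists of p53 targets (-0.36, 0.0268) and oxidative phosphorylation (-0.28, 0.0084) were lower, and interferon response (0.37, 0.000915) and proliferation (0.16, 0.0104) higher, with 5, 2, 1 and 1 genes adjusted over the list alone. All 5 calls were lost with an estimated correlation (adjusted p = 0.707), and those of proliferation and oxidative phosphorylation also against random lists (0.101 and 0.227). EZH2 (0.99 ± 0.27, adjusted p = 0.0288), BUB1B (1.09 ± 0.24), OASL (0.93 ± 0.26) and SESN2 (-0.90 ± 0.25) passed. CDKN1A did not pass (-1.23 ± 0.45, adjusted p = 0.118). limma called 476 genes, 185 higher and 291 lower, and leaving out each unit in turn gave 288 to 616. Quantile normalization and a fit without the unit block raised the count beyond that range. Scaling to the median gene lowered the share of higher genes. The interferon median was -0.21 without 1 of the 4 units and -0.24 in the 2 units of series 2, so that list rests on 1 unit. The p53 signature had fewer steps than NFT in 4 of 4 units (log2 difference -0.792), and 221 genes passed with steps as a covariate. With only the 4 units in the fit 13 genes passed; ARL9 (1.92, adjusted p = 0.0252), MT1G (1.78, 0.0436) and PAX2 (-2.31, 0.00148) kept their calls, the other 13 named genes that had passed lost theirs, and the proliferation call was lost (adjusted p = 0.0678).

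Stroma beside STIC was compared with stroma beside NFT in 11 units, and stroma beside STIL in 16, to ask whether the tissue next to a lesion changes. limma called 0 genes in both, with 1173 and 793 at an unadjusted p below 0.05. As lists, type I interferon genes were higher beside STIC (median 0.25, adjusted p = 1.08e-10, list mean higher in 11 of 11 units; 5 of 38 adjusted over the list alone; adjusted p = 0.093 with an estimated correlation). IFI6 (0.76 ± 0.20, adjusted p = 0.307, higher in 10 of 11) and BST2 (0.60 ± 0.16, adjusted p = 0.345) were its strongest members. MHC class II (median 0.27, adjusted p = 8.45e-06), MHC class I (0.15, 0.000103), macrophages (0.21, 0.000217), T and NK cells (0.14, 0.00485) and oxidative phosphorylation (0.07, 0.0242) were higher as lists, at adjusted p between 0.275 and 0.512 with an estimated correlation, and the class I and oxidative phosphorylation calls were also lost against random lists (0.0929 and 0.856). The complement gene C1QC (0.78 ± 0.22, adjusted p = 0.525, higher in 11 of 11) and HLA-F (0.75 ± 0.20, adjusted p = 0.307) are members that did not pass. Ciliated cell genes were lower beside STIC (median -0.24, adjusted p = 1.44e-09; 0.00036 with an estimated correlation; 12 of 40 adjusted over the list alone), TPPP3 by 0.88 ± 0.20 without passing (adjusted p = 0.307). In series 3 (6 units) the oxidative phosphorylation median was -0.04, and in series 2 (4 units) that of T and NK cells was -0.06.

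Beside STIL, MHC class II (median 0.24, adjusted p = 0.000824), T and NK cell (0.16, 0.000824), MHC class I (0.15, 0.0113) and macrophage genes (0.08, 0.0394) were higher as lists, and smooth muscle genes lower (-0.26, 2.93e-05), at adjusted p between 0.371 and 0.677 with an estimated correlation; the macrophage call was also lost against random lists (0.207). Ciliated cell genes were lower (median -0.16, adjusted p = 1.75e-08; 0.00067 with an estimated correlation; 4 of 40 adjusted over the list alone), CAPS by 0.59 ± 0.15 and FOXJ1 by 0.43 ± 0.15 without passing (adjusted p = 1 for both). Stroma beside STIC had more steps in 8 of 11 units (log2 difference 0.176), and beside STIL in 10 of 16 (0.00859).

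Stroma beside HGSC was compared with that beside NFT in the shared stromal fit, with both in 3 units. C3 (2.89 ± 0.61), MGP (2.67 ± 0.51), APOE (2.32 ± 0.41), C1QC (2.21 ± 0.38), C4B, which has a near-identical copy (2.01 ± 0.37), and the interferon gene IFI6 (1.96 ± 0.34) were the largest rises, each in 3 of 3 units. F3, tissue factor (-1.69 ± 0.30), CHGB (-1.44 ± 0.32), LCNL1 (-1.42 ± 0.33), CRISP3 (-1.42 ± 0.33), PRRT1 (-1.41 ± 0.34) and IGFBP5 (-1.32 ± 0.29) were the largest falls. Macrophage genes rose for 8 of 17 (13 adjusted over the list alone; median 1.25, adjusted p = 6.09e-26; 0.000136 with an estimated correlation), interferon genes for 3 of 38 (15 adjusted over the list alone; 0.61, 5.82e-21), MHC class I genes for 2 of 17 (10 adjusted over the list alone; 0.74, 2.05e-12) and MHC class II genes for 1 of 13 (8 adjusted over the list alone; 1.07, 1.67e-14). The last 3 calls held with an estimated correlation (0.00322, 0.0208 and 0.0215), and IFI30 (1.89 ± 0.34) and HLA-B (1.37 ± 0.31) are members. Serous carcinoma markers (median 0.18, adjusted p = 6.2e-05) and glycolysis genes (0.37, 0.00213) were higher and ciliated cell genes lower (-0.42, 1.36e-10), and held with an estimated correlation (0.00489, 0.0357 and 0.000136). The serous call was lost against random lists (0.538), and STMN1 of that list rose by 1.40 ± 0.32.

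Further lists higher beside HGSC were B and plasma cells (median 0.57, adjusted p = 2.37e-06), oxidative phosphorylation (0.28, 6.19e-05), matrix (0.28, 0.00494), T and NK cells (0.32, 0.00689), secretory cells (0.26, 0.00945), smooth muscle (0.29, 0.00945), mesothelium (0.06, 0.0248) and keratins and junctions (0.07, 0.0249), while immediate early genes were lower (-0.33, 0.0118). None of these 9 held with an estimated correlation (adjusted p between 0.05 and 0.358). All but B and plasma cells, T and NK cells and immediate early genes were also lost against random lists (adjusted p between 0.149 and 0.642). The keratin list mean was higher in only 1 of 3 units. The immunoglobulin gene IGHG1 did not pass (3.69 ± 1.15, adjusted p = 0.232), but did with only the 3 units in the fit (3.89, adjusted p = 0.00459). limma called 82 genes, 63 higher and 19 lower. Leaving out each unit in turn gave 17 to 59, and leaving out stroma of differing diagnosis 24. Without 1 of the 3 units the immediate early median was 0.22 and that of smooth muscle turned. Without another, the medians of secretory cells, keratins and mesothelium turned. Stroma beside HGSC had more steps in 3 of 3 units (log2 difference 0.542), and 40 genes passed with steps as a covariate. With only the 3 units in the fit 44 genes passed and C3 was 2.45; IFI6, STMN1, CHGB, LCNL1, CRISP3, PRRT1 and IGFBP5 no longer passed, nor did the keratin list (adjusted p = 0.159).

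The change from NFT to STIC was compared between epithelium and stroma in the 11 units that held all 4 kinds of region. limma called 237 genes whose change differed, 74 with a higher and 163 with a lower change in epithelium. Both the count and the share with a higher change fell with quantile normalization. The change of STMN1 was higher in epithelium by 2.18 ± 0.39, of KRT7 by 2.07 ± 0.39, of MEX3A by 1.99 ± 0.32, of H1-3 by 1.86 ± 0.31, of H3C2 by 1.83 ± 0.35 and of DBN1 by 1.81 ± 0.33. It was lower for ODF3B (-2.74 ± 0.42), IGFBP7 (-2.73 ± 0.39), AK1 (-2.73 ± 0.44), C9orf24 (-2.62 ± 0.42), C20orf85 (-2.60 ± 0.52) and AGR2 (-2.45 ± 0.47). Ciliated cell genes had a lower change in epithelium for 23 of 40 (37 adjusted over the list alone; median -1.46, adjusted p = 3.04e-41). Proliferation (0.56, 3.63e-11), serous carcinoma (0.57, 1.16e-06), DNA replication (0.32, 0.000312), Fanconi repair (0.35, 0.00108), keratin (0.32, 0.0051) and p53 target genes (-0.21, 0.00272) differed as well. Adjusted over the list alone, 14, 11, 6, 0, 4 and 2 of their genes passed in that direction. All 7 calls held with an estimated correlation, at adjusted p of 0.0459 or less, and the keratin call was lost against random lists (0.36) and with quantile normalization (0.226).

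MHC class II genes had a lower change in epithelium than in stroma for 3 of 13 (9 adjusted over the list alone; median -1.12, adjusted p = 6.74e-10; adjusted p = 0.0849 with an estimated correlation), HLA-DRA by 1.74 ± 0.40 and CTSS by 1.93 ± 0.37. The lists of interferon response (median -0.27, adjusted p = 0.000312), MHC class I (-0.34, 0.00351), steroid response (-0.30, 0.0101), T and NK cells (-0.23, 0.00998) and macrophages (-0.23, 0.0227) also had a lower change in epithelium, and these were lost with an estimated correlation (adjusted p between 0.141 and 0.478). With steps as a covariate 0 genes passed in limma (1786 at an unadjusted p below 0.05), the list calls other than ciliated cells and MHC class II were lost, and the medians of class I (0.38) and serous genes (-0.08) turned. The case-coded slides (8 units), series 2 (4 units) and series 3 (6 units) each gave 0 genes in limma, with 1953, 1421 and 1242 at an unadjusted p below 0.05.

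**Figure D4:**
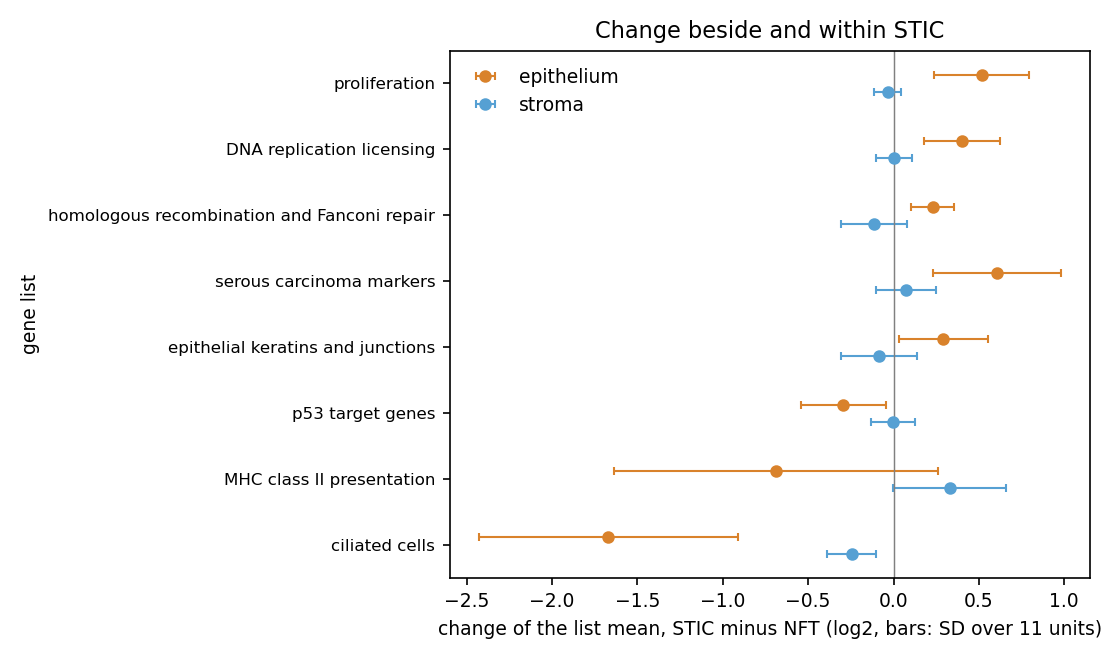
Change of the list mean from NFT to STIC (horizontal axis, log2) in epithelium and in stroma of the same 11 units for 8 gene lists (vertical axis); points are means over units and bars the SD. The ciliated change is lower in epithelium than in stroma by 1.43 and the MHC class II change by 1.01.

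Whether lesion and stroma changed together was asked in 22 units with STIC or STIL, over 7 lists. The MHC class II change of the lesion correlated with that of its stroma at Pearson r = 0.42 (permutation p = 0.0524, adjusted p = 0.367) and Spearman rho = 0.6 (permutation p = 0.00366, adjusted p = 0.0256), two-sided. Without the 2 units farthest from the median r was 0.504. Within series 3 (14 units) r was 0.451 (permutation p = 0.106, adjusted p = 0.201) and rho 0.701 (permutation p = 0.00724, adjusted p = 0.0507), so the rank correlation no longer passed, while series 2 held 4 units, too few to test. With STIL alone (15 units) r was 0.596 (permutation p = 0.0153, adjusted p = 0.107) and rho 0.804 (permutation p = 0.00064, adjusted p = 0.00448). For the other 6 lists, which were interferon response, MHC class I, proliferation, T and NK cells, B and plasma cells and macrophages, adjusted p was 0.655 or more for r and 0.812 or more for rho.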

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

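The tests of depth and of immune cells for the class II genes, of depth for the macrophage and matrix genes, and of less epithelium for the ciliated genes were chosen after the results were seen; for depth, a fit of the 5 groups was added once a regression over the units, read first, had not excluded it.

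The STIC change differed between epithelium and stroma for 8 of 26 lists, tested by exact sign flips of the difference of the list means in 11 units. It was higher in epithelium for proliferation by 0.551 (SD 0.281, 10 of 11 units), DNA replication by 0.396 (SD 0.222, 11 of 11), Fanconi repair by 0.343 (SD 0.186, 10 of 11), serous carcinoma markers by 0.532 (SD 0.343, 10 of 11) and keratins and junctions by 0.378 (SD 0.183, 11 of 11). It was lower in epithelium for ciliated cells (-1.43, SD 0.713, 11 of 11) and p53 targets (-0.29, SD 0.201, 10 of 11). The exact sign-flip test gave these 7 lists an adjusted p of 0.00724. The MHC class II difference was -1.01 (SD 0.981, 9 of 11 units, adjusted p = 0.0286), with means of -0.687 in epithelium and 0.328 in stroma. With steps as a covariate only the camera calls of ciliated cells (median -1.19, adjusted p = 7.77e-11) and MHC class II (-0.878, 0.0305) were kept. The medians of proliferation (0.291), DNA replication (0.187), Fanconi repair (0.199), keratins (0.226) and p53 targets (-0.15) shrank and that of the serous list turned to -0.0821, at adjusted p between 0.418 and 0.878, so depth may have a part in these 6.

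In 1 of the 4 units with a p53 signature, 3 of 26 lists stood far from the other units: type I interferon response (1.31 against -0.0237 to 0.0204; gap over range 0.967), MHC class I (0.395 against -0.22 to -0.17; 0.919) and endothelium (0.437 against -0.067 to -0.0387; 0.944). Chance alone sets apart about 1 list in 20.

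MHC class II genes fell in STIC epithelium by a mean of 0.59 ± 0.157 (SE, 27 units), and the list call was lost with an estimated correlation (adjusted p = 0.408) and within series 3 (median -0.3, adjusted p = 0.248). For depth, the regression over the 27 units on steps, read first, gave -0.368 ± 0.296, too wide to decide. In the fit of the 5 groups with steps as a covariate, added after that value was seen, the fall was larger (-0.964 ± 0.208), which argues against depth as the whole cause, and a part played by depth stays open. Fewer immune cells in the regions cannot be told apart from lower class II expression in the lesion cells. Of the 49 markers of macrophages, T, NK, B and plasma cells, 38 lie no higher than the olfactory 95th percentile in NFT epithelium, all 18 T and NK cell markers among them, and could hardly fall further. The other 11, 4 of macrophages and 7 of B and plasma cells, changed by 0.0898 ± 0.11, which is 0.679 ± 0.156 above the class II change but covers too few of the markers to decide. The loss of another class II-bearing cell type was not tested.

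Macrophage and matrix genes were higher in HGSC than STIC epithelium by 0.458 ± 0.126 (13 units, higher in 11). Ordinary tubal stroma mixed into the HGSC regions would raise the genes that mark it, but the 50 genes highest in stroma beside NFT, outside the lists, changed by -0.055 ± 0.0626, which is 0.513 ± 0.124 below. For depth, the regression over the 13 units on steps, read first, gave 0.138 ± 0.196, within 1 SE of 0 as depth would predict. In the fit of the 5 groups with steps as a covariate, added after that value was seen, the difference was 0.372 ± 0.105, which argues against depth as the whole cause, and the regression leaves a part played by depth open. Macrophages and fibroblasts that differ from those of normal tube, caught with the tumour, and expression by the tumour cells both stay open and were not tested. In the 2 case-coded units the macrophage median was -0.0432 and the matrix median -0.0787.

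Ciliated cell genes were lower in stroma beside STIC by 0.245 ± 0.043 (SE), in 11 of 11 units. A candidate explanation is epithelial RNA in the stromal regions that came from STIC in place of NFT. The 943 genes outside the list that were higher in epithelium and rose in STIC changed in this stroma by 0.121 ± 0.0459, against 0.0811 if they were carried over in the same proportion as the ciliated genes. They were picked as higher in epithelium than in stroma, and stroma beside NFT is also the baseline of their change. The picking itself can therefore favour a rise. Less epithelium of any kind cannot be told apart from no such change, because the keratin and junction list changed by -0.0861 ± 0.067. That list rose by 0.292 in STIC epithelium of these 11 units, so carry-over would raise it in the stroma, where it did not rise. A change within stromal cells was not tested.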

How the results depend on the processing

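The alternatives with steps as a covariate, with genes above the olfactory level only, without batch 3_1, without the region of another batch and with only the units that hold both groups, and the relation within batch series, were tests chosen after the results were seen. The main limits are depth, which rose from NFT to HGSC in 13 of 13 units, a background near which most genes lie, the small number of units for the p53 signature (4) and for stroma beside HGSC (3), and microarray units that average over patients.

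Of the counts of called genes under an alternative, 120 stayed within 1.5 times the count given in the report and 60 did not. Of the values of named genes, 3080 stayed on their side of the threshold and, if called, kept direction, 452 were lost, 5 gained and 2 turned. Of the list values, 4206 did the same, 242 were lost, 153 gained and 46 turned. Among those kept are all 260 list values with weights by regions. Camera did not take the weights there, so no call could be lost and only a median could turn. A value called in neither the report nor the alternative was counted as kept whatever its direction. Of the 286 list tests, 76 calls were lost with an estimated correlation, a setting in which a turn of direction was not assessed. Against random lists 28 were lost, 28 gained and 5 turned. Scaling to the median gene, leaving out batch 1, batch 3_1, the region of another batch, or the genes of the lowest mean levels moved no count by more than 1.5 times. Of the correlations of lesion and stroma, only the rank correlation of MHC class II passed in the report (rho 0.6, adjusted p = 0.0256). It passed with STIL alone (0.804, adjusted p = 0.00448) and was lost within series 3 (0.701, adjusted p = 0.0507; 14 units). Correlations that passed in no setting changed sign for interferon with STIL alone (r 0.049 in place of -0.196, rho 0.05 in place of -0.205) and for MHC class I with STIL alone (r 0.374 in place of -0.018, rho 0.439 in place of -0.0435) and within series 3 (r 0.0592). Counts below follow the setting. Values of lists are medians, given where the median or the test turned for a list called in the report or in the setting. The cause was not tested, except that some settings leave fewer units or genes, as stated.

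Quantile normalization gave 1165 genes for the p53 signature (476 in the report), 698 for STIC against STIL (1286), 44 for HGSC against STIC (74), 33 for stroma beside HGSC (82), 4438 for epithelium against stroma (7038) and 82 for the epithelium and stroma difference (237). Its MHC class I median for epithelium against stroma was -0.166. The share of higher genes moved from 65.7% to 55% for HGSC against NFT, from 74.7% to 59.3% for STIC against STIL, from 71.6% to 61.4% for HGSC against STIC and from 31.2% to 6.1% for the epithelium and stroma difference. Scaling to the median gene moved it from 38.9% to 21.7% for the p53 signature and from 52.9% to 73.6% for epithelium against stroma.

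With only the 2 groups of a comparison in the units that hold both, 13 genes passed for the p53 signature, 365 for STIC against STIL, 20 for HGSC against STIC and 44 beside HGSC, fits with fewer units and groups to estimate the spread. The p53 target median of HGSC against STIC was 0.0603 there. For epithelium of STIC, STIL and HGSC against NFT no named gene or list call was lost.

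With no replicate block, so that averages were not paired by unit, 1110 genes passed for the p53 signature, 423 for STIC against STIL and 7 for stroma beside HGSC, where the immediate early median was 0.187 and that of mesothelium -0.0266. With the slide in place of the case, 364 genes passed for the epithelium and stroma difference (12 units). With regions as samples, 163 passed for the p53 signature, 3581 for STIC against STIL, 461 for HGSC against STIC and 10902 for epithelium against stroma. The list tests of that setting left out the unit, so they took the regions of a unit as independent samples. Those tests turned for keratins in STIC (median 0.128), immediate early genes in STIL (-0.0384) and, beside HGSC, immediate early genes (-0.152), keratins (-0.0562) and matrix (0.0722). Weighting by regions gave 4622 for STIL, 7094 for HGSC, 4800 for STIC against STIL, 633 for HGSC against STIC, 2, 5 and 211 for stroma beside STIC, STIL and HGSC, and 12307 for epithelium against stroma.

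On case-coded slides, with fewer units, 2757 genes passed for STIC (16 units), 1012 for STIL (16), 383 for HGSC (2), 56 for the p53 signature (4), 188 for STIC against STIL (7), 12 for HGSC against STIC (2) and in limma 0 for the epithelium and stroma difference (8; 1953 unadjusted). There the mesenchymal median of HGSC against NFT was -0.0231, and for HGSC against STIC the medians were interferon -0.105, mesenchymal -0.0153, matrix -0.0787, T and NK cells -0.046, macrophages -0.0432 and mesothelium -0.166, with TBX2 at 0.426. Without batch 1 the steroid median of HGSC against STIC was 0.0148.

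In series 2, 1185 genes passed for STIL (11 units), 611 for STIC against STIL (11), 2 for stroma beside STIL (2), 19 for stroma beside HGSC (2), 792 for epithelium against stroma (4) and in limma 0 for the epithelium and stroma difference (4; 1421 unadjusted). Medians that turned were interferon in the p53 signature (-0.239), steroid response in HGSC against STIC (0.024), T and NK cells beside STIC (-0.0558) and, beside HGSC, keratins (-0.114) and mesothelium (-0.0473). In series 3, 724 genes passed for STIC (7), 405 for STIL (9), 45 for the p53 signature (2), and in limma 0 for STIC against STIL (2; 1318 unadjusted) and 0 for the epithelium and stroma difference (6; 1242 unadjusted). There CDKN2A in STIC was -0.24, and the lists that turned were class II (-0.0237) and matrix (-0.0109) in STIL, interferon (0.0463) and macrophages (-0.189) in STIC against STIL, oxidative phosphorylation beside STIC (-0.0361) and MHC class I in the epithelium and stroma difference (0.0448).

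Without the tenth of regions with the fewest steps, 724 genes passed for the p53 signature (3 units) and 441 for the epithelium and stroma difference (9). Without stroma of differing diagnosis, 24 passed beside HGSC (2 units), with medians of -0.0955 for secretory cells, -0.0285 for keratins and -0.0472 for mesothelium. Leaving out each unit in turn gave 288 to 616 genes for the p53 signature, the lowest without replicate 2, and an interferon median of -0.211 (without replicate 2) to 0.666. Replicate numbers here only count the units left out and differ from those of the sample labels. Beside HGSC it gave 17 to 59 genes, 22 without replicate 1 and 17 without replicate 2. Medians ran there from -0.0463 to 0.54 for secretory cells, -0.0139 to 0.292 for keratins and -0.0836 to 0.32 for mesothelium, each lowest without replicate 1, and from -0.837 to 0.218 for immediate early genes and -0.0402 to 0.473 for smooth muscle, turning without replicate 2.

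With only the 7489 genes above the olfactory level tested, 3346 passed for STIC, 248 for the p53 signature and 3700 for epithelium against stroma; list tests turned for serous (0.0795) and mesenchymal genes (-0.0117) in HGSC against STIC, mesothelium beside STIC (0.284) and proliferation in epithelium against stroma (0.0155). With steps as a covariate, 2813 passed for STIC, 1384 for HGSC, 221 for the p53 signature, 332 for STIC against STIL, 33 for HGSC against STIC, 40 beside HGSC and in limma 0 for the epithelium and stroma difference (1786 unadjusted). The serous median of HGSC against STIC was then -0.0186, and in the epithelium and stroma difference the tests turned for interferon (-0.0429), MHC class I (0.384), serous (-0.0821) and steroid genes (-0.176). Against random lists, medians lay on the other side for oxidative phosphorylation in STIC (0.203), keratins beside HGSC (0.0709) and, in epithelium against stroma, serous (0.22), steroid (-0.085) and immediate early genes (0.152). Other pseudocounts and the count-based tests were not run, since the values are already log2, and subsets that left 1 unit are not given.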

Other observations

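The test of neighbouring genes on chromosomes was chosen after the result was seen, as was the set of histone genes.

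Histone genes, many of which are transcribed during DNA replication, stood out beyond the largest rises. Of 71 histone genes measured, 56 were higher and 1 lower in STIC than NFT (median 0.718), 22 and 1 in STIL (0.281) and 56 and 1 in HGSC (0.882), and 32 were higher and 0 lower in STIC than STIL (0.463) in limma. The medians stayed above 0 with quantile normalization (0.635, 0.285, 0.7 and 0.308) and with scaling to the median gene (0.725, 0.28, 0.911 and 0.471). In the p53 signature limma called 0 of the 71 (median 0.0588). Many histone genes are near-identical, so the number called may count 1 signal more than once. A candidate explanation is more cell division in STIC: over 27 units the histone change went with the change of the proliferation list at Pearson r = 0.622 (permutation p = 0.00034) and Spearman rho = 0.583 (permutation p = 0.00158). The correlation was 0.511 without the 2 farthest units, 0.67 within series 2 (19 units) and 0.434 within series 3 (7 units). Depth rises in STIC as well and was not separated from division by that test.

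STIC regions of one unit resembled each other more than those of other units of the same batch for 9 of 26 lists, in 41 regions of 11 case-coded units and 7 batches (10000 permutations within batches). After removal of batch means, the share of variance between units was 65.6% for immediate early genes, 62% for ciliated cells, 60.7% for steroid response, 60.3% for cholesterol synthesis, 48.3% for serous carcinoma markers, 47.6% for matrix, 44.4% for MHC class II, 41.1% for mesothelium and 35.1% for proliferation, at adjusted permutation p from 0.0013 to 0.0387. Permuted shares had medians of 10.9% to 15.2% for these lists. The slide and the case cannot be separated here.

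A hypothesis of DNA copy number that differs between the STIC of different units was tested on 7404 genes above background. If it holds, genes near each other on a chromosome change together across units. The mean correlation of the STIC changes of genes 1 to 10 Mb apart was 0.102 ± 0.00578 (jackknife SE over chromosomes), and the highest of 100 shuffles of the genes was 0.00116. These shuffles replaced a rotation of gene order, named first, after values had been seen. It was 0.0531 in STIL, 0.142 in HGSC and 0.0377 in NFT regions set against NFT regions of the same unit, so the excess of STIC over NFT was 0.0639 ± 0.00618. At 20 to 40 Mb it was 0.0561 ± 0.0152 in STIC, 0.038 in STIL, 0.0713 in HGSC and 0.0279 in NFT, an excess in STIC of 0.0282 ± 0.0121. These values may reflect copy number, but the noise of the sets differs and no copy number was measured.

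The 4 mesothelium regions, from 1 unit, had a mesothelium list mean of 4.76 against 3.16 in the 5 NFT regions of that slide. Their keratin and junction mean was 4.99 against 6.22, the ciliated mean 2.75 against 4.83 and the MHC class II mean 5.85 against 4.23.

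The group labels were swapped within the units that hold both groups, and limma was run again. Other units of a shared fit kept their labels, and a split that swaps few units keeps part of the real contrast. The counts of other splits are therefore not counts by chance alone. For 7 comparisons only the real split of 100 gave as many genes, a share under 0.05. These were STIC against NFT (5344, highest other 2754), STIL against NFT (2360, 487), HGSC against NFT (4562, 2287) and STIC against STIL (1286, 768). The others were HGSC against STIC (74, 5), epithelium against stroma (7038, 2655) and the epithelium and stroma difference (237, 0). The median of the other splits was 0 in each of these 7. For stroma beside STIC and beside STIL the real count in limma was 0 (1173 and 793 at an unadjusted p below 0.05), so every one of the 100 splits was as large by construction (highest other 1 and 0). The swaps test nothing there and chance is not excluded for these counts; the list results for this stroma were not part of the swaps. The p53 signature (8 splits, 476 genes, highest other 345, median of the others 71) and stroma beside HGSC (4 splits, 82 genes, highest other 2, median of the others 0) had too few splits for a share under 0.05.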
